A study of Homo sapiens with 3 samples.

How the data were processed

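ERRα ChIP-seq of BT474 cells was available as 2 full peak lists, one for cells exposed to vehicle and one for cells exposed to 0.5 mM AICAR, both for 90 min. Groups were taken from the sample labels. The design text of the series describes a longer treatment and microarrays, so treatment and time follow the sample labels. Each peak workbook was tied to its sample by the match of its name with the sample title, where control stands for vehicle. The sample titles call each library merged and 1 peak list per condition was used, so replicates cannot be compared. The input library was not analysed here. Per the submitters' processing notes, the tools were BWA 0.5.9, MACS 1.4.1 and HOMER 3.18, and the genome build was hg19. The notes used here give no order, role or parameters, and whether the input served as control in peak calling is not given in the sources used here.

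The deposited tables hold, per the file headers, the position of each peak, its peak score, its annotation class, the distance to the nearest TSS and the name and Entrez ID of that gene. The unit of the peak score is not stated in the headers, so it was treated as a score with no unit, and it was used only to rank or filter peaks within a list. Scores began at 50 in both lists, and the value 3100 was repeated among the highest scores, in 206 vehicle and 598 AICAR peaks. CpG content, GC content and conservation were deposited by the authors as fractions from 0 to 1 per peak. GC and CpG content are given here as percentages. Number of reads per library is not given in the sources used here, so the depth is unknown. A library of greater depth, or other calling parameters, can give more and weaker peaks, which affects the comparison of list sizes directly.

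The 7 deposited tables include copies limited by distance to the TSS. Each of these was an exact subset of its full list, at 20000 bp or 10000 bp, so the full lists were used. A last line without a peak, holding a column mean, was left out of each full list. Some gene symbols appeared as dates, for 24 vehicle and 35 AICAR peaks, and were restored from their Entrez IDs. Another 6 vehicle and 14 AICAR peaks had no gene. Coordinates are hg19 as in the lists, counted from 1, and widths include both ends.

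A peak was shared when it overlapped a peak of the other list by at least 1 bp. The same number of 18717 shared AICAR peaks was obtained with bedtools 2.31.1. For the overlap by chance, one list was shifted along each chromosome by a random distance 100 times. Score quartiles were formed within each list. A gene had a peak when a peak assigned to it lay within 10000 bp of its TSS. Each peak is assigned to 1 gene only in these lists, so a gene can lack a peak because a neighbour is closer to it. The peak of 31 AICAR-only genes and 30 vehicle-only genes overlapped a peak of the other list. That peak was assigned to another gene for 18 and 23 of them, and to the same gene beyond 10000 bp for the other 13 and 7.

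The universe for gene lists was 20052 protein-coding genes of a RefSeq table for GRCh38.p14, used for names and gene types only. Of 10671 Entrez IDs in the lists, 10622 were in that table. All 556 symbols of the 18 gene lists were matched, 328 by the symbol in the files, 217 by the current symbol and 11 by an older one. Each list's count was placed among those of 10000 random lists of the same size, which describes these lists and is no test between conditions. Lists share a few members, such as MTR, SHMT1, SHMT2, TYMS and SDHA. The genes named were chosen by a rule fixed before the data were examined. It takes the 8 highest-scoring shared, AICAR-only and vehicle-only peaks with a gene within 10000 bp, and up to 4 members of each list ranked highest in either list. It also takes every one-carbon gene, and ESRRA, PPARGC1A, PPARGC1B and ERBB2. Members with a peak in one condition only that are named beyond this rule (among them those of oxidative phosphorylation, ESR1, TFAP2B, MTOR, RRAGC, MEF2A, GABPB1, NME1 and MAT2A) were chosen after their values were seen. Some genes that the rule takes are not reported here.

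With 1 merged library per condition no test between conditions was run. Shares have exact Clopper-Pearson 95% intervals over peaks or genes, which cover counting error only. Width ratios have 95% percentile intervals from 1000 bootstrap draws of peaks. Both kinds assume independent peaks and cover no spread between libraries. Overlap and list scripts were tested on simulated data. All 9853 planted overlaps were recovered, a planted list reached the highest percentile, and 2.0% of 200 unplanted lists exceeded the 97.5th percentile. The alternatives fixed before the data were examined were stricter score limits, other overlap rules, lists of equal length, other distances to the TSS and another gene universe. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The share of peaks with an ERR response element was not computed, since no hg19 sequence was used here.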

Results

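Genome-wide binding of the estrogen-related receptor α (ERRα, encoded by ESRRA), an orphan nuclear receptor that regulates genes of mitochondrial energy metabolism, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in BT474 cells, a HER2-positive luminal human breast cancer cell line. Cells were exposed for 90 min to vehicle or to 0.5 mM AICAR, a cell-permeable compound that is converted in cells to an AMP mimic and activates the energy sensor AMPK. The study is about the PGC-1α/ERRα axis, one-carbon metabolism and the response to anti-folates, and the design sets ERRα binding after AICAR against binding after vehicle. Each condition was represented by 1 merged library and 1 peak list, without replicate lists. A library of input DNA completes the 3 samples and was not analysed here. The read depth of the libraries was not given in the sources used here, so differences in depth between the lists are unknown. Intervals of shares are exact binomial 95% intervals over peaks or genes and cover counting error only. Those of width ratios are bootstrap intervals over peaks. No difference between the conditions could be set against a spread between replicates.

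The ESRRA locus itself was bound in both conditions. The vehicle peak spanned chromosome 11, 64071320 to 64073132 (hg19), in the promoter at -818 bp from the transcription start site (TSS). The AICAR peak overlapped it and spanned 64071144 to 64075512, with its centre in intron 1 at 284 bp. A second, weaker vehicle peak in intron 2 (64078158 to 64079089, score 87.0) overlapped no AICAR peak. The overlapping peaks both had a peak score of 3100, a value repeated among the highest scores of both lists, so their heights cannot be ranked further. A site in intron 1 of COX7A2, a subunit of cytochrome c oxidase, ranked 15 of 34581 AICAR peaks, and one at the promoter of ATP5B, a subunit of the mitochondrial ATP synthase, had the repeated score of 3100 in both lists. Further high-ranking shared sites near a gene lay at ADAM2, CALCR (the calcitonin receptor), GALK1 (galactokinase), LOC100422737, C1orf74, STS (steroid sulfatase) and the promoter of C1orf151. Scores were the authors' own and were used only to order peaks within a list.

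The vehicle list held 22538 peaks and the AICAR list 34581, which is 1.53 times as many. AICAR peaks were also wider, with a median of 1358 bp against 877.5 bp, and covered 55.8 Mb of the genome against 22.9 Mb. Of the vehicle peaks, 19424 (86.2%, 85.7 to 86.6) overlapped an AICAR peak by at least 1 bp. Of the AICAR peaks, 18717 (54.1%, 53.6 to 54.7) overlapped a vehicle peak. When one list was shifted at random along the chromosomes 100 times, on average 3.14% of vehicle peaks and 2.02% of AICAR peaks overlapped, and at most 3.54% and 2.30%. Sharing increased with peak score. In the top score quartile 99.6% (99.4 to 99.7) of vehicle peaks and 97.1% (96.7 to 97.4) of AICAR peaks were shared. In the lowest quartile the shares were 62.4% (61.1 to 63.6) and 16.4% (15.6 to 17.2). With the stricter demand that peak centres lie within 100 bp, 51.9% of vehicle and 33.9% of AICAR peaks were shared.

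**Figure D1:**
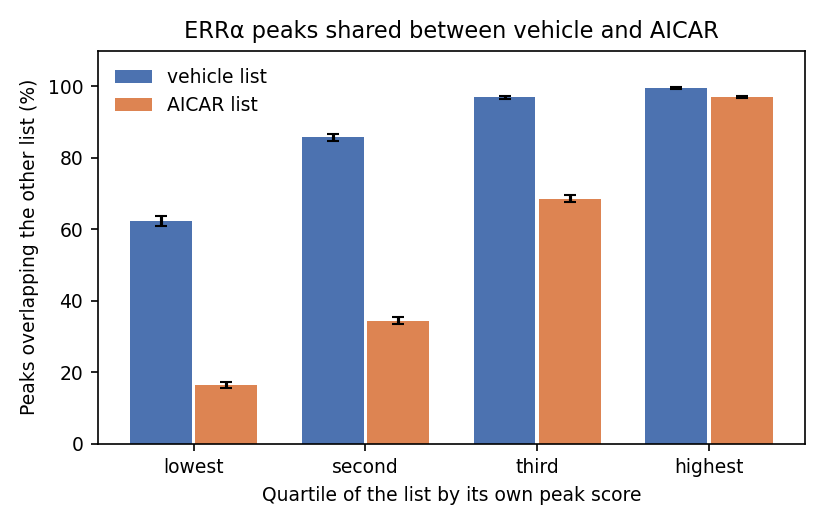
Percentage of peaks that overlap a peak of the other list by at least 1 bp (y axis) by score quartile of the list they belong to (x axis), for the vehicle list (blue) and the AICAR list (orange). Error bars are exact binomial 95% intervals; the shared part goes from 62.4% in the lowest to 99.6% in the highest quartile of vehicle peaks and from 16.4% to 97.1% of AICAR peaks.

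The 15864 AICAR-only peaks had a median score of 81.1, against 287.2 for shared peaks of the same list, and 254 of them were in its top score quartile. The highest-scoring ones near a gene lay in intron 10 of ARHGAP32 (chromosome 11, 128887777 to 128889251, score 960.7, rank 3028) and in intron 1 of EEF1A1, a translation elongation factor (chromosome 6, 74229246 to 74231399, score 618.5, rank 4792). The next were at the promoters of RBM18, RNF128 and TNPO2, in introns of CRNDE and ELAVL4, and upstream of FOXJ3.

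The 3114 vehicle-only peaks had a median score of 62.6, and 23 of them were in the top quartile of the vehicle list. The strongest near a gene lay in intron 1 of EPN3 (chromosome 17, 48607775 to 48614255, score 739.7), at the promoter of TOB1, an antiproliferative gene (chromosome 17, 48940424 to 48943175, score 560.2), and near ZNF217, an oncogene often amplified in breast cancer (chromosome 20, 52207134 to 52210196, score 482.3). Others were in intron 2 of UCP2, a mitochondrial carrier, near OR13G1, the progesterone receptor gene PGR and DLX3, and at the promoter of SDHA, a subunit of succinate dehydrogenase (chromosome 5, 218253 to 219690, score 283.8). The 23 peaks were wide, with a median of 3344 bp against 1166 bp for shared vehicle peaks of the same quartile, and 15 of them (65.2%) lay on chromosomes 11, 17 and 20, against 10.7% of those shared peaks. These chromosomes were singled out after the values were seen. PGR lies in a 5 Mb window, chromosome 11 from 100 to 105 Mb, where 44 of 86 vehicle peaks were vehicle-only.

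Most ERRα peaks lay away from promoters in both conditions. Within 1000 bp of a TSS lay 1426 vehicle peaks (6.33%, 6.01 to 6.65) and 1831 AICAR peaks (5.29%, 5.06 to 5.54). By the authors' annotation, 41.6% of vehicle and 41.3% of AICAR peaks were intronic, 51.5% and 52.8% were intergenic, and 4.10% and 3.40% carried the promoter class. Shared peaks were near a TSS in 6.46% (6.11 to 6.81, vehicle list) and 6.56% (6.21 to 6.92, AICAR list) of cases. For AICAR-only peaks the share was 3.81% (3.51 to 4.12), below both intervals, and for vehicle-only peaks 5.52% (4.75 to 6.38). The share followed peak score within each list. It was 4.95% (4.40 to 5.55) in the lowest and 8.50% (7.79 to 9.26) in the highest quartile of vehicle peaks, and 4.0% (3.60 to 4.44) and 6.67% (6.16 to 7.22) of AICAR peaks.

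**Figure D2:**
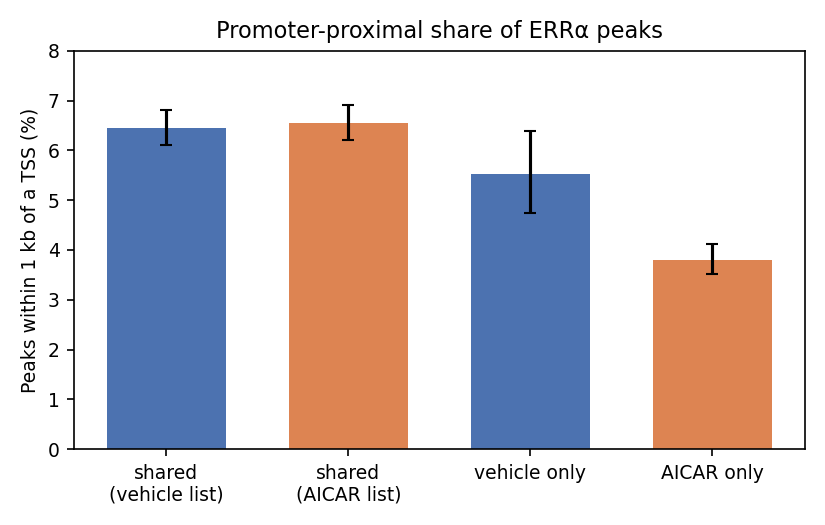
Percentage of ERRα peaks within 1000 bp of a TSS (y axis) for peaks shared between the lists, counted in each list, and for peaks of one list only (x axis), with vehicle in blue and AICAR in orange. Error bars are exact binomial 95% intervals; AICAR-only peaks are lowest at 3.81%, and shared peaks are at 6.46% and 6.56%.

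At gene level, 3677 genes had a vehicle peak within 10000 bp of their TSS and 4931 had an AICAR peak, of which 3295 had both. Thus 89.6% of the genes bound after vehicle were also bound after AICAR, while 1636 genes had an AICAR peak only and 382 a vehicle peak only. Among 20052 protein-coding genes the shares with a peak were 16.5% and 22.1%. The larger number for AICAR followed the longer list. With the AICAR list limited to its 22538 highest-scoring peaks, 3563 genes had an AICAR peak, fewer than the 3677 of the vehicle list. With peaks within 1000 bp, 1401 genes had a vehicle peak, 1802 an AICAR peak and 1158 both.

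Genes of mitochondrial energy metabolism were bound in large part in both conditions. Of 82 oxidative phosphorylation genes, 54 (65.9%, 54.6 to 76.0) had a vehicle peak, 50 (61.0%, 49.6 to 71.6) an AICAR peak and 48 both. ATP5B, ATP5G3 and ATP5A1 of the ATP synthase and COX7A2 ranked highest. NDUFA10, NDUFA13, NDUFB1, NDUFV3 and SDHA had a vehicle peak only and NDUFA7 an AICAR peak only. NDUFS1 and NDUFB9 also appeared in one list only, but their peaks overlapped a peak of the other list that was assigned to another gene. Of 30 genes of the TCA cycle and pyruvate dehydrogenase, 19 (63.3%, 43.9 to 80.1) had a vehicle peak and 16 (53.3%, 34.3 to 71.7) an AICAR peak. All 16 were among the 19. IDH2, the mitochondrial NADP-dependent isocitrate dehydrogenase, had a peak in intron 1 at chromosome 15, 90638098 to 90639548 (vehicle coordinates), with a score of 3100 in either list. IDH3A and MDH1 were also in the top score quartile of both lists. DLST, FH and SDHA had a vehicle peak only.

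Genes of fatty acid oxidation, glycolysis and the mitochondrial ribosome also carried peaks in both conditions. Of 27 fatty acid oxidation genes, 10 had a vehicle peak, 12 an AICAR peak and 9 both, and with equal numbers of peaks 9 had an AICAR peak. CPT1A, the rate-controlling carnitine palmitoyltransferase of mitochondrial fatty acid import, had a shared peak at chromosome 11, 68610712 to 68612124 (vehicle coordinates), and ECI2, ETFA and DECR1 were also shared. Of 23 glycolysis genes, 14 (60.9%, 38.5 to 80.3) had a peak in each list and 13 in both, with ALDOA, PKM, ENO1 and HK1 highest. Of 64 mitochondrial ribosomal protein genes, 30 had a vehicle peak, 31 an AICAR peak and 25 both, including MRPL34, MRPL12, MRPL35 and MRPL15. With equal numbers of peaks, 22 of the 64 were bound after AICAR. Of 75 cytosolic ribosomal protein genes, 7 (9.33%, 3.84 to 18.3) had a vehicle peak and 13 (17.3%, 9.57 to 27.8) an AICAR peak. RPS19 and RPL21 were bound in both lists, and RPL3 after AICAR only.

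Set against 10000 random lists of as many protein-coding genes, 6 of the 18 lists fixed beforehand had more bound members than 97.5% of random lists, and the same 6 did so in both conditions. They were oxidative phosphorylation, the TCA cycle, glycolysis, the mitochondrial ribosome, fatty acid oxidation and the luminal breast cancer list. Fatty acid oxidation was the lowest of these, above 99.2% of random lists after vehicle and 99.1% after AICAR. The cytosolic ribosome list exceeded only 2.67% of random lists after vehicle and 12.0% after AICAR. Within 1000 bp, however, it exceeded 64.3% and 90.2%, fatty acid oxidation 91.0% and 93.2%, and the ERR and PGC-1 circuit 99.2% and 99.4%. The counts after vehicle and after AICAR within 1000 bp were 53 and 47 for oxidative phosphorylation, 16 and 13 for the TCA cycle, 25 and 24 for the mitochondrial ribosome and 12 in both for glycolysis. They were smaller for fatty acid oxidation, with 4 and 5, and for the luminal list, with 6 and 8. Distances run from the peak centre, so a wider AICAR peak can shift a shared site across the 1000 bp limit. The highest-scoring peaks at ERBB3 and GREB1, both shared, lay at -1214 and -1537 bp in the vehicle list. In the AICAR list they lay at -307 and -872 bp. When random lists were drawn only from the 9316 coding genes nearest to a peak, the fatty acid oxidation list was above 95.9% and 95.3% of them, and the TCA cycle list after AICAR above 92.6%. The cytosolic ribosome list was then above 23.3% and 74.0% of them.

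Genes of one-carbon and folate metabolism were bound about as often as random lists. Of 28 genes, 4 (14.3%, 4.03 to 32.7) had a vehicle peak and 7 (25%, 10.7 to 44.9) an AICAR peak, above 30.5% and 57.6% of random lists. DHFRL1, MTHFD2 and MTRR were bound in both conditions. DHFRL1 had a promoter peak at chromosome 3, 93781212 to 93782288 (vehicle coordinates). The MTHFD2 peak, at a gene of mitochondrial folate metabolism, lay in intron 3 at chromosome 2, 74432652 to 74433698. The peak at MTRR, methionine synthase reductase, lay at 9287 bp from the TSS at chromosome 5, 7877811 to 7879197. With peaks within 1000 bp only, the counts were 1 after vehicle and 4 after AICAR.

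Peaks within 10000 bp after AICAR only were found at MTHFD1, MTR, MTHFD2L and FTCD. Of these genes, MTR also had vehicle peaks farther away, the nearest a shared one at 49338 bp. At MTHFD1, the trifunctional cytosolic folate enzyme, the peak spanned chromosome 14, 64854726 to 64856514, in intron 1 at 861 bp from the TSS, with a score of 137.9 (rank 17227). At MTR, methionine synthase, it spanned chromosome 1, 236957690 to 236960318, over exon 1, with a score of 191.4 (rank 13516). The MTHFD2L peak covered the promoter at chromosome 4, 75022345 to 75023920 (score 119.7), and the FTCD peak lay in intron 7 at chromosome 21, 47568170 to 47569234 (score 112.9). ALDH1L1, 10-formyltetrahydrofolate dehydrogenase, had a vehicle peak only, of score 53.6, close to the list minimum of 50. All 4 genes with an AICAR-only peak kept it in the equal-length lists.

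The other 20 one-carbon genes had no assigned peak within 10000 bp in either list. Among them were TYMS, the thymidylate synthase inhibited by fluoropyrimidines, and SHMT1, SHMT2, FPGS, GLDC, AMT, GCSH, ALDH1L2, DMGDH, SARDH, MTFMT, MTHFS, FOLR1, SLC25A32 and SLC46A1. GCSH, MTHFS and SARDH had an assigned peak only farther away. For GGH, SLC19A1 and MTHFD1L it was closer by. The peak of GGH, which hydrolyses folate polyglutamates, was shared and lay at 19624 bp from the TSS in the vehicle list. The reduced folate carrier SLC19A1 had a shared peak at 20913 bp, and MTHFD1L an AICAR-only peak at 16593 bp.

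Pathways that feed or use one-carbon units had counts within the range of random lists in both conditions. Of 8 serine and glycine synthesis genes, PHGDH and SLC1A4 were bound in both, and none had a peak within 1000 bp in either list. PHGDH, the first enzyme of serine synthesis from glycolysis, had an intron 1 peak at chromosome 1, 120260717 to 120261787 (vehicle coordinates), in the top quartile of both lists. De novo purine synthesis had 3 of 13 genes bound in each list, with PRPS1 and GMPS shared, GART after vehicle only and IMPDH1 after AICAR only. Pyrimidine and deoxynucleotide synthesis had 2 of 14 genes bound after vehicle (RRM2 and NME2) and 5 after AICAR, with NME1, RRM2B and DUT added. With equal numbers of peaks it had 2 genes bound after AICAR (NME2 and RRM2B), as many as after vehicle, while RRM2 was no longer bound after AICAR. In the methionine cycle 3 of 11 genes were bound after vehicle (MAT1A, AHCY and AHCYL1) and 5 after AICAR, with MTR and MAT2A added. Within 1000 bp its counts were 0 after vehicle and 1 after AICAR.

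In the ERR and PGC-1 circuit, 5 of 21 genes had a vehicle peak and 8 an AICAR peak. ESRRA, GABPA, NR0B2 and SIRT5 were among those shared. PPARGC1B, encoding the coactivator PGC-1β, had an AICAR-only peak in intron 1 at chromosome 5, 149159368 to 149160820 (score 216.1, rank 12292), and GABPB1 and MEF2A were also AICAR-only. PPARGC1A, encoding PGC-1α, had a shared intronic peak at 12119 bp from the TSS in the vehicle list, outside the 10000 bp limit. Of 26 AMPK and mTOR signalling genes, 6 had a vehicle peak and 8 an AICAR peak, among them SESN1, STK11, RPTOR and PRKAG2 in both and MTOR and RRAGC after AICAR only. Within 1000 bp the counts of this list were 1 after vehicle and 5 after AICAR. Peak width contributed to this. At SESN1, a shared site, the centre lay at 2001 bp in the vehicle list and at 658 bp in the AICAR list, with widths of 2028 and 5168 bp. Lipid and cholesterol synthesis had 5 and 7 of 22 genes bound, with SREBF1, SREBF2 and FASN in both.

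Luminal breast cancer genes were among the most often bound, with 17 of 27 (63.0%, 42.4 to 80.6) in each list and 15 in both. KRT8, EHF, ERBB3 and GREB1 ranked highest. The estrogen receptor gene ESR1 had an AICAR-only promoter peak (chromosome 6, 152010280 to 152011641, score 311), TFAP2B was also AICAR-only, and PGR had a vehicle-only peak. ERBB2, encoding HER2, had no peak assigned to it at any distance in either list. Of 18 circadian clock genes, 4 were bound after vehicle (TEF, NR1D1, ARNTL and CRY1) and 3 after AICAR, the latter without CRY1. Control lists stayed within the range of random lists in both conditions. Marker genes of other lineages had 6 of 45 members bound after vehicle and 11 after AICAR, and basal and stromal markers had COL1A2, PECAM1 and TP63 bound out of 20 in both. With equal numbers of peaks, 1 of these 20 was bound after AICAR.

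**Figure D3:**
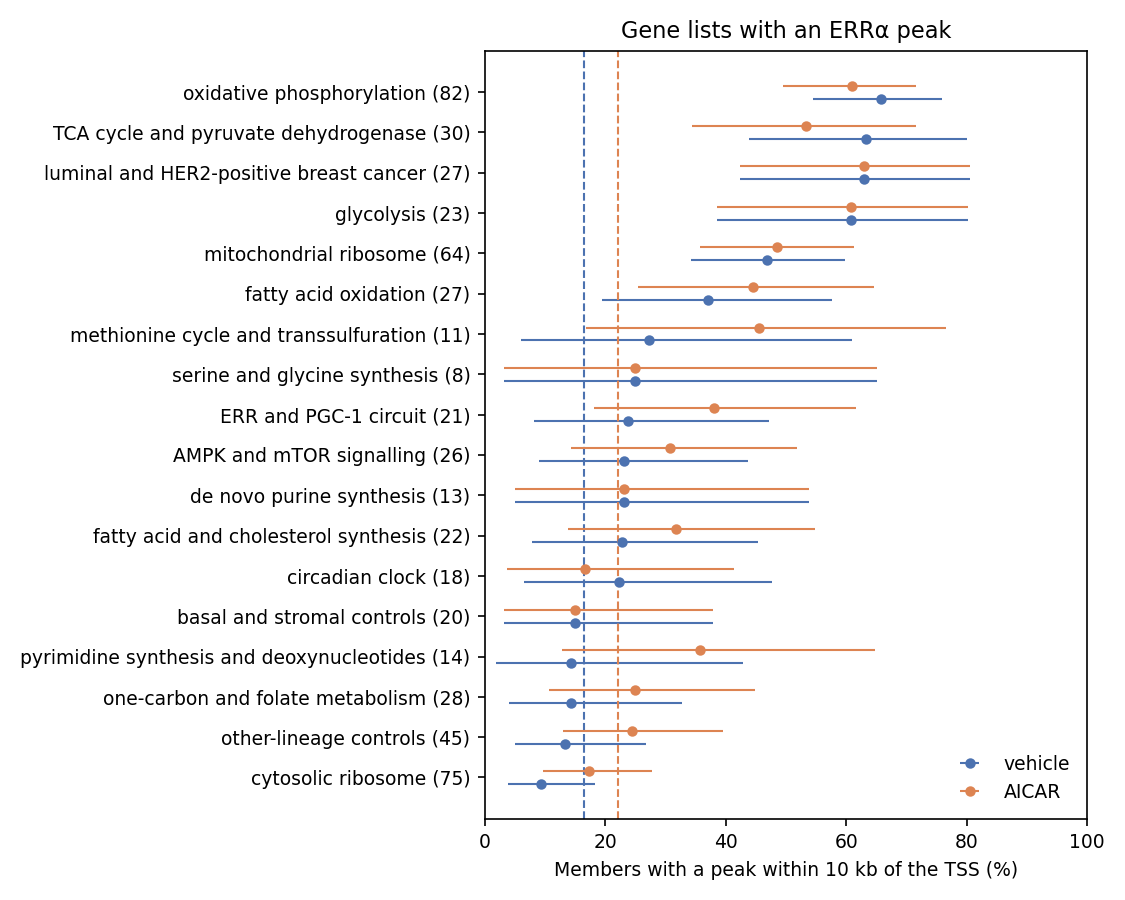
Percentage of the members of each gene list (number of members in parentheses, y axis) with an ERRα peak within 10000 bp of the TSS (x axis), after vehicle (blue) and after AICAR (orange). Horizontal lines are exact binomial 95% intervals and dashed lines mark all protein-coding genes, at 16.5% for vehicle and 22.1% for AICAR; the energy metabolism lists and the luminal list lie to the right of them, and one-carbon metabolism lies at 14.3% and 25%.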

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

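Of the alternatives run, 4 were chosen after the data were seen: a peak score of at least 100, peaks resized to 500 bp, and overlap or genes without the 5 Mb windows rich in vehicle-only peaks. Stricter score limits shorten the lists by construction, to 11270 vehicle and 17291 AICAR peaks at or above the list median, 5634 and 8645 in the top quartile, and 12684 and 21625 at a score of at least 100. Only the limit of 100 could have turned the order of the lists, and AICAR stayed the longer one there. That limit sets the same score for both lists, while shared peaks had a median score of 287.2 in the AICAR list and 134.1 in the vehicle list. It is therefore no independent check on list length. Of vehicle and AICAR peaks, the shared percentages were 63.2 and 41.2 with 50% reciprocal overlap, 51.9 and 33.9 with centres within 100 bp, and 87.0 and 56.0 with a gap of up to 1000 bp. They were 75.9 and 72.7 with equal numbers of peaks, 92.5 and 58.9 in the upper 50% of each list, and 94.1 and 60.3 in the top quartile. With peaks resized to 500 bp they were 77.0 and 50.1, and without the windows 88.0 and 55.0. The vehicle share was the higher one under every one of these. All but the equal-number setting kept the AICAR list longer, so the order there mostly followed list length. Wider TSS distances take in more peaks by construction, 13.5% and 12.0% at 5000 bp and 20.1% and 18.1% at 10000 bp. The TSS share was 7.21% and 5.99% in the upper 50% of each list, and 5.80% of AICAR peaks with equal numbers. Genes with a vehicle peak, an AICAR peak and both numbered 1401, 1802 and 1158 within 1000 bp, and 2203, 2834 and 2010 in the upper 50% of each list. With 20000 bp, equal numbers, the authors' distance-limited tables or without the windows they stayed within 1.5 times of the reported counts. With equal numbers, however, AICAR had fewer genes (3563) than vehicle (3677). The number of lists above 97.5% of random lists was 6 in both conditions at 20000 bp, at 1000 bp and with equal numbers. At 1000 bp the ERR and PGC-1 circuit took the place of fatty acid oxidation. It was 5 after vehicle and 4 after AICAR with random lists from genes nearest to a peak. One-carbon genes numbered 1 after vehicle and 4 after AICAR within 1000 bp, and 4 and 7 with equal numbers. Of the 34 counts for the other lists, 33 were lower within 1000 bp, 27 higher within 20000 bp and 15 lower with equal numbers. Within 1000 bp 21 of the 34 changed by more than 1.5 times, and 6 lost all peaks. Among named genes, 5 of 236 peak counts went to 0 with equal numbers and 84 within 1000 bp. With equal numbers the vehicle list stayed whole, so only AICAR counts could change in that setting. The search for ERR elements and its alternatives was not run, for want of an hg19 sequence here. No paired analysis was possible because each condition had 1 merged library. The cause of these differences was not tested beyond what the settings fix by construction. Unknown read depth limits every comparison of list lengths.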

Other observations

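L1 content differed between shared and condition-specific peaks. The centre of the peak lay in an L1 element, a family of autonomous retrotransposons, in 16.2% (14.9 to 17.5) of vehicle-only peaks and 11.8% (11.3 to 12.3) of AICAR-only peaks. For shared peaks this was 6.08% (5.75 to 6.43) in the vehicle list and 6.29% (5.95 to 6.65) in the AICAR list. L1 shares were also higher in the lowest score quartile of each list, at 11.5% and 12.1%, than in the highest, at 4.21% and 6.07%. MIR elements, ancient short retrotransposons, held the centre of 8.27% (7.87 to 8.67) of shared and 5.28% (4.94 to 5.64) of AICAR-only peaks of the AICAR list. In the vehicle list the intervals of shared peaks, 9.11% (8.71 to 9.53), and vehicle-only peaks, 8.48% (7.52 to 9.51), overlapped. The median GC content was 37.7% for both vehicle-only and AICAR-only peaks, and 41.3% for shared peaks in either list.

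Among genes without a vehicle peak, 8.70% of coding genes had an AICAR peak. Pyrimidine and deoxynucleotide synthesis had 3 of 12 such genes with an AICAR peak, and the mitochondrial ribosome 6 of 34, where random draws gave as many in 7.54% and 7.15% of cases. With equal numbers of peaks these counts were 1 of 12 and 3 of 34, with as many in 34.1% and 11.2% of draws. Oxidative phosphorylation kept a peak at 48 of 54 genes bound after vehicle, and the TCA cycle at 16 of 19. Random draws of vehicle-bound coding genes kept as few in 44.8% and 28.7% of cases. So the vehicle-only members of these energy lists were about as many as such draws give.

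In what follows, the tests on the longer, wider AICAR list and on the windows were chosen after those results were seen, as were the test of one-carbon gains at equal list length and the use of the equal-number list against the longer list, while the other tests on one-carbon genes were chosen before. The AICAR list was 1.53 times longer and its peaks 1.55 times wider at the median. New strong sites, taken as the top AICAR score quartile, do not account for this, since 2.94% of AICAR peaks in it lacked a vehicle peak. In the next lower quartile 31.4% lacked one, so new sites of moderate score were not excluded. At 18025 sites paired one to one the AICAR peak was wider by a median of 539 bp. The largest median gain of the 4 vehicle score quartiles was 1.15 times the smallest (1.13 to 1.18). That lies within the limit set for a fixed extension of every peak, as a longer fragment or shift size in peak calling gives. Medians cannot show that every peak gained the same length, and single shared sites differed. The GMPS peak went from 1166 to 1280 bp and the ETFA peak from 904 to 3471 bp. A fixed extension thus stays open. Whether such an extension also changes the number of peaks called was not tested. A deeper or more sensitive AICAR library cannot be told apart from more weak sites after AICAR, because depth is unknown, and 37.6% of vehicle peaks in the lowest quartile lacked an AICAR peak, between the under 10% set for greater depth and the over 50% set against it.

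Vehicle-only peaks were concentrated in a few regions. Of 466 windows of 5 Mb with at least 20 vehicle peaks, 21 had a vehicle-only share of 33.3% or more, while 1000 random draws matched on score quartile gave at most 6. This argues against loss of binding site by site regardless of region as the account of all vehicle-only peaks. For the 2549 vehicle-only peaks outside the 21 windows such loss stays open. These windows held 18.1% of vehicle-only peaks and 5.56% of all vehicle peaks, with 45 of 70 vehicle-only on chromosome 17 from 50 to 55 Mb and 44 of 86 on chromosome 11 from 100 to 105 Mb, around PGR. The window on chromosome 17 held 52 AICAR peaks, fewer than the 70 vehicle peaks. On chromosome 8 from 110 to 115 Mb there were 179 AICAR against 90 vehicle peaks, and 131 of the 179 were AICAR-only. In the whole AICAR list 45.9% were AICAR-only. Some of these windows thus held more AICAR than vehicle peaks, with many unshared peaks in both lists. Vehicle-only peaks inside them were 1.41 times as wide (1.33 to 1.55) as those outside, with medians of 1007 and 712 bp, beyond the ratio set for regional background. However, 9 of the 21 windows carried this, with medians of 1002 to 3299 bp, among them the windows named on chromosomes 17 and 11. The other 12, among them the window named on chromosome 8, had medians of 543 to 879 bp. Regional background, such as extra DNA copies, called differently in the lists stays open, under a demand for most windows that was added after their widths were seen, since DNA copy number was not analysed here, and a regional response to AICAR was not tested.

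Of the 24 one-carbon genes without a vehicle peak, 4 had an AICAR peak (MTHFD1, MTR, MTHFD2L and FTCD), and 15.4% of random draws of 24 such coding genes from the full AICAR list had as many or more. That share met the 5% set beforehand for the longer AICAR list alone, but this test kept the extra length. Without it, in the equal-number list, 0 of the 4 genes lost the AICAR peak. This argues only against AICAR peaks below the lowest score kept, 94.36, which include those near the AICAR calling threshold, as the source of the 4 gains. The MTHFD2L and FTCD peaks, at 119.7 and 112.9, still scored below the AICAR list median of 137.3. Peaks of the weaker part of the list were thus not excluded, and the test set beforehand was met. The equal-number list also cannot show whether these sites lay just under the vehicle calling threshold, so a difference in sensitivity between the lists stays open. In the equal-number list 3.44% of coding genes without a vehicle peak had an AICAR peak, and 0.92% of random draws had 4 or more of 24, with a mean of 0.828. This was the lowest value of the 18 lists, and the control list of other lineages had 4.57%, so with 18 lists compared a chance gain at equal list length cannot be told apart from a response to AICAR. One merged library per condition keeps this open, and such a response is a hypothesis only.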
